A study of Spodoptera frugiperda with 6 samples.

How the data were processed

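Poly(A)-selected RNA from 6 pools of fall armyworm midguts was sequenced on the SOLiD 3 Plus, a platform that records colours between neighbouring bases, from a strand-specific kit. Per the series' design text, larvae were kept at 27 °C, 14 h light and 10 h dark and 70% humidity, and midguts were taken 2 days after the molt to the last instar. The authors pooled 3 µg of RNA from each of 12 to 13 midguts per library, and gave RNA integrity numbers of 8.3 to 9.7 and an estimated ribosomal RNA content of 3.2% to 6.1%. The pools hold different larvae, so p-values rest on the spread between deposited columns of pools of one rearing. At contigs that passed the test below, the median coefficient of variation of the columns was 2.19% on Tx601 and 1.56% on Mp708. Other contigs of like abundance had 13.16% and 12.43%. SE and p-values of the contigs that passed may therefore not reflect the variation between pools of larvae.

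Per the design text, the authors kept reads of median score 12 or more with 25 or more bases and at least 1 base of score 14 or more. They assembled 138911 Sanger sequence tags into contigs with SeqMan Pro 8.0.2 and mapped each library with the Bowtie-like algorithm of NextGENe, requiring 85% of 12 or more nucleotides to match and placing each read once. The submitters' processing notes name Bowtie and edgeR 2.6.7. The deposited raw counts are whole reads per contig for 6136 contigs, and per the file headers contigs with fewer than 20 counts over the 3 libraries of either line had been removed. The deposited mean normalized values are scores made by the authors as means of TMM-scaled counts rounded to whole numbers, per the file headers. The deposited p-value column comes from the authors' two-tailed paired tests without adjustment, per the file headers, and the pairing is not given in the sources used here. The deposited fold is the ratio of the authors' mean normalized values, Mp708 over Tx601, and the deposited log2 column is its log2, per the file headers. The authors' deposited table gave 457 contigs with p under 0.05, 233 higher and 224 lower on Mp708. The authors' log2 fold and the fitted one had r = 0.999 across contigs. The 6 deposited columns of normalized values per library were not used.

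Groups were taken from the sample titles. One label names both maize lines as susceptible, while the source label and the series title call Mp708 resistant. The table's Tx601 column A has no matching title (the third Tx601 title carries the letter M), so it was used as a Tx601 library without a link to a sample. The letters are not shared between lines, so nothing was paired. Replicates were compared by a chi-square of their counts: the lowest mean per contig within a line was 37.8, where sampling alone gives 1, so no library was counted as a repeat of another.

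Counts were analysed with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, glmQLFit and glmQLFTest, two-sided, Benjamini-Hochberg adjusted p under 0.05). SE is the log2 fold divided by the square root of F. CPM values, computed here from the deposited counts, use TMM factors. These differed by line, from 1.11 to 1.15 on Tx601 and from 0.86 to 0.94 on Mp708. Fixed lists of description words (23 lists and 7 marker lists of other tissues) were tested with camera of limma 3.58.1 at a preset correlation of 0.01 on log2 CPM with a prior count of 2, again with an estimated correlation, and with fry. Lists under 5 contigs had no set test, and adjustment ran over the 29 lists tested. A contig may be in several lists, and cytochrome b5 and vacuolar ATP synthase words fall under respiration too. Names are the UniProtKB descriptions that the deposited table pairs with contigs; 2541 name a protein. The supplied gene table for another assembly shares no identifiers with the contigs and was not used. On simulated counts for the 3 against 3 comparison (5899 contigs tested), 55 of 100 contigs changed by a factor of 2 and 97 of 100 changed by a factor of 4 were recovered, with 6 unchanged contigs among 158 calls.

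The rule for named contigs, fixed with the lists and tests before the data were examined, took the 12 largest rises and falls past the threshold whose libraries did not overlap between lines and whose description names a protein; the 2 members of each list with the smallest p; 8 peritrophic contigs and every chitin synthase; 2 rises and 2 falls without such a description; and the 5 most abundant contigs. Contigs of one description are counted separately. Cysteine proteases, contigs called in both sources and contigs called in the recount were also followed under the alternatives. Similar contigs share reads, so values of single members of a family are uncertain.

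The 4 deposited read files (Tx601 M and B, Mp708 E and F; reads of Tx601 C and Mp708 D were not analysed here) held 15908341, 20370290, 21520341 and 13635824 colour-space reads. They were counted again, an analysis chosen after the data were seen. The primer base and first colour were dropped, exact windows of 20 colours were matched to the deposited contig sequences in both orientations, and each read went to the contig with the most windows, ties shared and sums rounded. Of the reads, 91.1% to 92.4% matched a contig, and 50.7% to 52.4% matched several. Further versions used reads matching a single contig, or any contig with a window of 16 colours. The recount was tested in the same way on 2 against 2 libraries, with camera at the preset correlation only. Depth set the precision: totals of 13346340 to 22516622 deposited counts leave counting error small for all but low contigs.

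Alternatives were DESeq2 1.42.0 size factors, upper-quartile factors, total counts alone, no filter, a mean of at least 50, DESeq2, the edgeR exact test, limma-trend, stricter thresholds, contigs summed by description, and each library left out.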

Results

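Fall armyworm (Spodoptera frugiperda, corn strain) is a moth whose larvae feed on maize. Larvae were reared from hatching on leaves of either Mp708, a resistant maize inbred, or Tx601, a susceptible inbred, and the midgut transcriptome of last-instar larvae was sequenced. Mp708 makes the cysteine protease Mir1-CP, which per the series title degrades the peritrophic membrane, the chitin and protein sheet that lines the insect midgut. The comparison asks which midgut transcripts differ between larvae on the 2 maize lines. Each line had 3 libraries, and each library came from a pool of 12 to 13 midguts of larvae weighing 300 to 400 mg. The deposited count columns are lettered A, B and C for Tx601 and D, E and F for Mp708. Their totals were 13346340, 16816645 and 14368325 counts for Tx601 and 20061952, 22516622 and 13622747 for Mp708, over 6136 assembled contigs. Of these contigs, 5951 were tested. No coordinates are given, because the contigs were assembled from expressed sequence tags and no genome was used.

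In the deposited counts, 104 contigs rose and 9 fell in larvae on Mp708 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, n = 3 per line). The median log2 fold was 2.01 among the rises and -1.01 among the falls. Most rises were in contigs for digestive enzymes and peritrophic membrane proteins. The reads of 4 libraries (Tx601 M and B, Mp708 E and F) were also deposited, and counting them again gave a different picture for most of these contigs. In that recount 27 contigs passed the same test, 23 higher and 4 lower, and 14 of the 113 contigs called in the deposited counts were among them. Fewer libraries entered the recount. The deposited columns A, B, E and F alone (column A has no link to Tx601 M) gave 123 calls, 23 of them shared with the recount, at the same common biological coefficient of variation of 0.17. The median recounted log2 fold of the 104 rises was 0.31, with quartiles of 0.15 and 0.81. Recounted values are therefore given beside the deposited log2 folds of named contigs and the tests of lists past the threshold. Scaling by total counts alone moved the median of all contigs by -0.34 on the log2 scale and gave 375 calls, only 96 of them higher. The medians of the peritrophic, chitin, exopeptidase, carbohydrate and lipase lists then turned to -0.15, -0.16, -0.15, -0.29 and -0.16, while against the median of all contigs they stayed at 0.20, 0.19, 0.20, 0.06 and 0.19, so directions of lists are relative to other contigs.

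**Figure D1:**
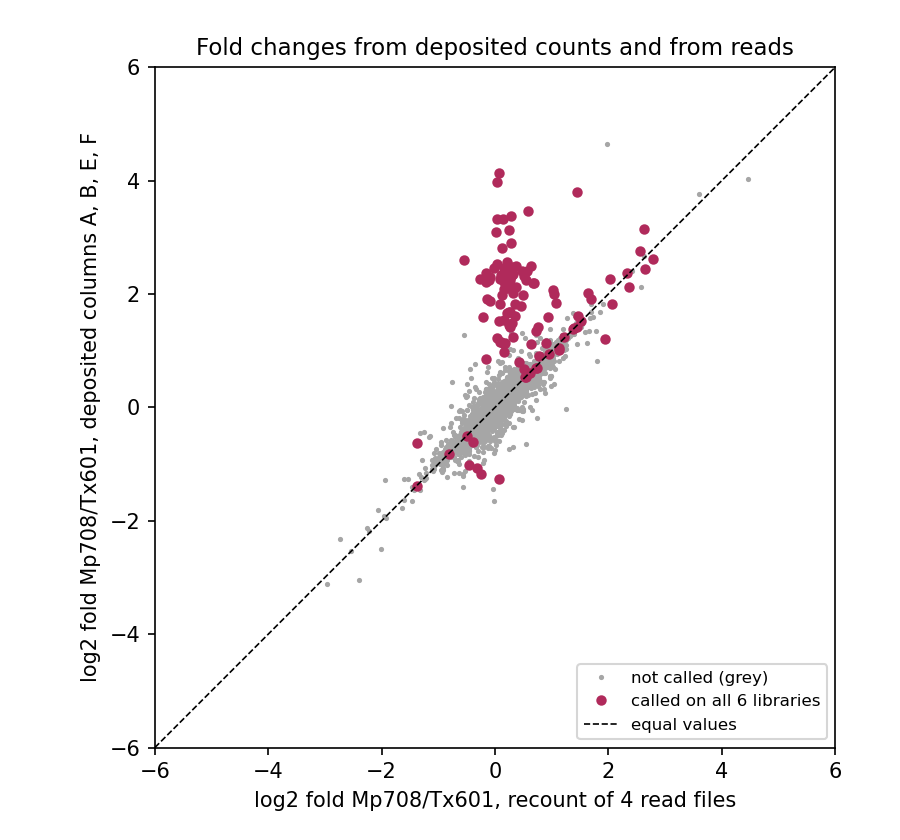
Log2 fold Mp708 over Tx601 per contig from the deposited columns A, B, E and F (vertical axis) against the recount of the 4 read files (horizontal axis). Grey points are contigs not called on all 6 libraries, coloured points are the 113 called contigs, and the dashed line marks equal values. The uncalled contigs lie along the line (r = 0.93 across contigs), while most called rises stand above it (r = 0.29 across the called contigs).

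Transcripts of peritrophic membrane proteins and intestinal mucins, the structural glycoproteins of that membrane, were among the largest rises in the deposited counts. Of the 33 contigs in this list, 11 rose, none fell and 22 did not pass the test. Adjusted over the list alone, 11 rose. Insect intestinal mucin IIM86 (Contig_5136) went from 501.8 ± 7.78 to 8738 ± 107 CPM (counts relative to the TMM-scaled library total; mean ± SD, n = 3 each). Its log2 fold was 4.12 (SE 0.08, edgeR adjusted p = 8.84e-08). Its recounted log2 fold was 0.07 (SE 0.16). Insect intestinal mucin 4 (Contig_7329) rose by 3.47 on the log2 scale and peritrophin type-A domain protein 4 (Contig_2452) by 2.80, against 0.58 and 0.13 in the recount. Peritrophin membrane protein 1 (Contig_1150) rose by 2.21, against -0.15 in the recount. Insect intestinal mucin 3 (Contig_2833) kept more of its rise, at 3.76 against 1.44 in the recount (SE 0.57), but was not called there. Its recounted Tx601 libraries were far apart, at 1.62 (M) and 10.42 (B) CPM, against 16.67 (E) and 16.79 (F) on Mp708. Over the 11 called members the median was 2.90 in the deposited counts and 0.28 in the recount. The list stood above other contigs in a camera test (adjusted p = 2.92e-14). It also did so with an estimated correlation (adjusted p = 0.0236) and, at the preset correlation, in the recount (adjusted p = 0.0309). Without the contigs whose counts and reads differ, an exclusion that takes out all 11 called members by its own rule, the adjusted p was 0.274.

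Chitin synthesis and turnover contigs showed the same contrast between the 2 sources. Of 7 measured, 3 rose and none fell, and 3 rose when adjusted over the list alone. Chitin synthase A (Contig_6500), an enzyme that polymerises chitin, had 1.94 ± 0.028 CPM on Tx601 and 30.3 ± 0.623 on Mp708. Whether it serves the peritrophic membrane was not tested. Counts were low, at 29, 37 and 31 on Tx601, with recounts of 31 and 38 on Tx601 and 52 and 18 on Mp708. The log2 fold of this contig was 3.97 in the deposited counts (SE 0.15, edgeR adjusted p = 1.10e-06) and 0.03 in the recount (SE 0.35). Chitin deacetylase 1 (Contig_5054), which removes acetyl groups from chitin, rose by 2.35 on the log2 scale, against 0.32 in the recount. The camera test gave an adjusted p of 3.25e-05. With an estimated correlation the adjusted p was 0.324, and in the recount it was 0.47.

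**Figure D2:**
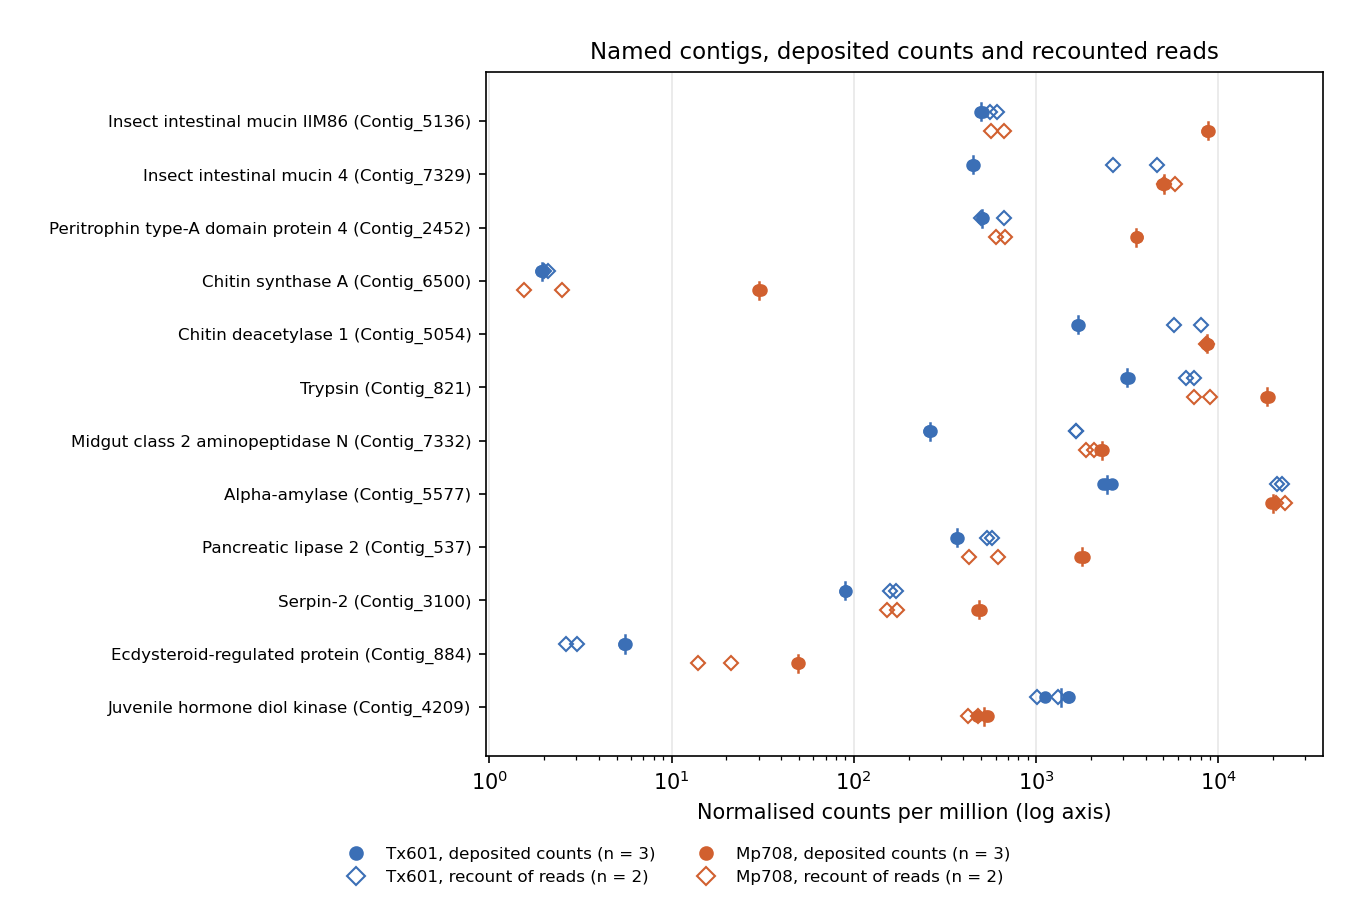
Normalised CPM (log axis) of 12 named contigs. Filled circles are the 3 deposited columns of each line with their mean as a bar, and open diamonds are the 2 recounted libraries of each line. In the mucin, peritrophin, chitin, trypsin, aminopeptidase, amylase, lipase and serpin contigs the filled circles of the 2 lines stand apart by more than the open diamonds do, while ecdysteroid-regulated protein and juvenile hormone diol kinase differ between the lines in both sources.

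Serine proteases, the main protein-digesting enzymes of the caterpillar gut, gave the largest group of rises. Of 77 contigs, 35 rose and none fell in the deposited counts, and 42 rose when adjusted over the list alone. A trypsin contig (Contig_821) went from 3172 ± 45.97 to 18620 ± 288 CPM, a log2 fold of 2.55 (SE 0.06, edgeR adjusted p = 2.65e-07), against 0.22 (SE 0.19) in the recount. Another trypsin contig (Contig_3972) rose by 2.53, against 0.04 in the recount. The called members had a median log2 fold of 1.86 in the deposited counts and 0.30 in the recount, where 1 member of the list was called. That member, trypsin IIb (Contig_2997), was named after its values were seen. It rose by 2.48 in the deposited counts (edgeR adjusted p = 2.67e-06) and by 2.79 in the recount (edgeR adjusted p = 0.00501). The list stood above other contigs by camera (adjusted p = 2.87e-46) and with an estimated correlation (adjusted p = 0.027). In the recount camera placed it higher at the preset correlation (adjusted p = 1.36e-10). List medians were 0.78 in the deposited counts and 0.31 in the recount.

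Other digestive groups followed. Among 35 exopeptidases 9 rose and none fell; adjusted over the list alone, 9 rose and 1 fell. Midgut class 2 aminopeptidase N (Contig_7332), which frees amino acids from peptide ends, rose by 3.13 on the log2 scale (SE 0.08, edgeR adjusted p = 2.65e-07), against 0.25 in the recount. Among 17 carbohydrate-digesting contigs 3 rose and none fell, and 3 rose adjusted over the list alone. Alpha-amylase (Contig_5577), which cleaves starch, rose by 3.02, against 0.01 in the recount. Its deposited counts were 46647 for Tx601 B and 425064 for Mp708 E, and its recounts were 429279 and 429199. Among 57 lipases and lipid carriers 8 rose and 1 fell; adjusted over the list alone, 13 rose and 2 fell. Pancreatic lipase 2 (Contig_537) rose by 2.28, against -0.08 in the recount, and a lipase contig (Contig_7270) fell by 0.56, against -0.49 in the recount. Camera gave adjusted p-values of 3.17e-06, 0.02 and 3.63e-06 for the 3 lists. With an estimated correlation the adjusted p-values were 0.0805, 0.324 and 0.0636. In the recount they were 0.527, 0.717 and 0.0896. The carbohydrate call was also lost without Tx601 A (adjusted p = 0.0678), Tx601 B (0.0584) or Mp708 F (0.0939) and with contigs of one description summed (0.508). Without the contigs whose counts and reads differ, which takes out called members by its own rule, the adjusted p-values of the 3 lists were 0.218, 0.993 and 0.00481.

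Among 26 protease inhibitors 3 rose and none fell, and 3 rose adjusted over the list alone. Serpin-2 (Contig_3100), an inhibitor of serine proteases, rose by 2.44 on the log2 scale and serpin 2 (Contig_4248) by 2.38, against -0.01 and -0.15 in the recount. The inhibitor list did not pass the camera test over 6 libraries (adjusted p = 0.287, median 0.05), but it passed upward in the recount (adjusted p = 0.0213, median 0.33), in the deposited columns A, B, E and F (0.00229) and without Tx601 C (0.018). These passes are at the preset correlation; with an estimated correlation over 6 libraries the adjusted p was 0.873. A cadherin-like membrane protein (Contig_3185) was the 1 rise among 31 contigs of the cytoskeleton and brush border, at 2.37 against 0.17 in the recount, and that list passed by fry (adjusted p = 0.0224) but not by camera (0.977) or with an estimated correlation (0.989). No cysteine or aspartic protease was called by the edgeR quasi-likelihood test over 6 libraries among 6 tested (3 at an unadjusted p under 0.05). The edgeR exact test and DESeq2 each called 2, and the quasi-likelihood test on columns A, B, E and F called 1. The list did not pass camera (adjusted p = 0.115, or 0.0218 without Tx601 C, and 0.695 with an estimated correlation over 6 libraries), and 2 were higher adjusted over the list alone. The pair were putative C1A cysteine protease contigs, Contig_1247 at 1.00 (SE 0.24) and Contig_7314 at 0.88 (SE 0.22), with recounted values of 1.34 and 1.14.

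A smaller set of contigs differed between the lines in both sources. The 14 contigs called in both were named after their values were seen. They held 5 contigs described as uridine diphosphate glucosyltransferase, an enzyme class that conjugates plant toxins to sugars, which the words of the detoxification list did not match. Of these, Contig_7605 rose by 2.71 on the log2 scale in the deposited counts and 2.55 in the recount, and Contig_5259 by 1.96 and 2.07. Ecdysteroid-regulated protein (Contig_884) rose by 3.16 (SE 0.14, edgeR adjusted p = 2.08e-06) and by 2.63 in the recount (SE 0.27, edgeR adjusted p = 0.00501). Juvenile hormone diol kinase (Contig_4209), which acts in the breakdown of juvenile hormone, fell by 1.42 (SE 0.14, edgeR adjusted p = 4.22e-04) and by 1.37 in the recount (SE 0.19, edgeR adjusted p = 0.0162). The others were 3 protease contigs, a second ecdysteroid-regulated protein, trypsin IIb and 2 phosphatidylethanolamine-binding proteins. Levels in the 2 sources could still differ. In Mp708 E, Contig_884 had 1053 deposited and 289 recounted counts and Contig_1463 had 12344 and 32525, while Contig_7605 had 1305 and 1330. Deposited columns also matched closely at Contig_884, with 5.53 ± 0.088 CPM on Tx601 from counts of 83, 106 and 88. Its deposited SE and p-value may therefore not reflect the variation between pools.

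Few contigs of the detoxification lists passed the test. These lists do not hold the uridine diphosphate glucosyltransferase contigs described above, which rose in both sources. Among 32 cytochrome P450 contigs, whose products oxidise plant toxins, 1 rose: Cyp6AB4 (Contig_4735), by 1.30 on the log2 scale (edgeR adjusted p = 0.0108), against 1.37 in the recount. Among 81 other detoxification contigs 1 rose and 1 fell. Glutathione S-transferase omega 2 (Contig_1544) rose by 0.66, against 0.53 in the recount, and glutathione S-transferase E2 (Contig_5635) fell by 1.28, against 0.07 in the recount. The 2 detoxification lists did not pass camera (adjusted p = 0.422 and 0.645), and adjusted over the list alone 1 P450 contig rose and, of the others, 2 rose and 1 fell. None of 32 antioxidant and none of 44 immune contigs passed the edgeR quasi-likelihood test (3 and 5 at an unadjusted p under 0.05, 0 and 1 called by DESeq2 and by the edgeR exact test), and neither list passed camera over 6 libraries (adjusted p = 0.211 and 0.67). The immune list passed upward in the recount (adjusted p = 0.0309, median 0.27), in the deposited columns A, B, E and F (0.04) and without Tx601 C (0.00198), each at the preset correlation. With an estimated correlation over 6 libraries the adjusted p was 0.953. No call was made in the lists for the proteasome and ubiquitin (60 contigs), glycolysis and the TCA cycle (29), the V-ATPase proton pump (23), membrane transporters (12), the secretory pathway (37) and growth and cell renewal (12), by edgeR, DESeq2 or limma-trend. These lists held 2, 1, 1, 2, 2 and 1 contigs at an unadjusted edgeR p under 0.05, and their camera adjusted p-values ran from 0.252 to 0.977. For the whole table, 484 contigs had an unadjusted edgeR p under 0.05.

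Lists for protein synthesis passed camera downward on Mp708 at the preset correlation but not with an estimated one, with small changes per contig. Of 163 ribosomal protein contigs 2 fell and none rose: 40S ribosomal protein S13 (Contig_7365) fell by 1.17 on the log2 scale and 40S ribosomal protein S25 (Contig_963) by 1.01, against -0.24 and -0.46 in the recount. The list's median was -0.22 in the deposited counts and -0.35 in the recount, with camera adjusted p-values of 8.01e-08 and 7.12e-19. With an estimated correlation the adjusted p for the deposited counts was 0.641. Translation factors had a median of -0.16 (camera adjusted p = 0.00521, 52 contigs, 5 at an unadjusted p under 0.05, no call by edgeR or DESeq2), heat shock proteins and chaperones -0.14 (adjusted p = 0.00794, 69 contigs, 4 at an unadjusted p under 0.05, no call by edgeR or DESeq2), and mitochondrial respiration -0.10 (adjusted p = 0.0231, 144 contigs, 1 fall). That fall was cytochrome b (Contig_1796), by 1.07, against -0.31 in the recount. With an estimated correlation the adjusted p was 0.727 for translation factors, 0.641 for heat shock proteins and 0.873 for respiration. In the recount the translation, heat shock and respiration lists had medians of -0.18, -0.07 and -0.16, and camera adjusted p-values of 0.00106, 0.0309 and 3.00e-05. With a library left out, the heat shock and translation calls were lost without Tx601 B (adjusted p = 0.137 and 0.235) or Mp708 D (0.202 and 0.0859), and the respiration call without Tx601 A (0.68), Tx601 B (0.196) or Mp708 F (0.468). The respiration call was also lost with contigs of one description summed (0.807) and without the contigs whose counts and reads differ (0.0584).

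Marker lists for tissues next to the midgut held no contig called by the edgeR quasi-likelihood test over the 6 deposited libraries. Visceral muscle contigs (25) had a median of -0.20 and a camera adjusted p of 0.00621, or an adjusted p of 0.393 with an estimated correlation, and -0.25 in the recount (camera adjusted p = 0.0112). Of them 6 had an unadjusted p under 0.05 and none was called by DESeq2, and without Mp708 E the adjusted p was 0.0735. Their share of all counts was 0.777% ± 0.00565 on Tx601 and 0.511% ± 0.00505 on Mp708 (0.767% and 0.608% in the recount), so it was lower where the ribosomal share was lower and the digestive share higher. The lists for hemocytes (16 contigs, adjusted p = 0.119), fat body (18, 0.827), cuticle, foregut and trachea (35, 0.67), nerve and endocrine cells (9, 0.827) and viruses, microbes or mobile elements (13, 0.67) did not pass camera over 6 libraries, and silk and salivary gland had 3 contigs, too few for a set test. At an unadjusted p under 0.05 there were 4, 1, 3, 0, 1 and 1 contigs in these 6 lists, and DESeq2 and the edgeR exact test each called 1 hemocyte and 1 cuticle contig. In columns A, B, E and F the quasi-likelihood test called 2 fat body contigs and 1 of the list for viruses, microbes or mobile elements as higher. The hemocyte list passed upward in the recount (camera adjusted p = 0.00452, median 0.56), in the deposited columns A, B, E and F (0.00445) and without Tx601 C (0.00376), and the fat body list without Tx601 C (0.0218), each at the preset correlation. With an estimated correlation over 6 libraries the adjusted p was 0.727 for hemocytes and 0.98 for fat body. The median, mean and camera direction differed in sign for fat body, with a median of 0.00, a mean of -0.29 and an upward test, and for the cytoskeleton, with -0.06, 0.05 and an upward test that did not pass (adjusted p = 0.977). They also differed for glycolysis, with -0.03, 0.01 and a downward test, for growth, with -0.05, 0.09 and a downward test, and for immune contigs, with -0.03, 0.00 and an upward test.

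Digestive transcripts took up a larger share of the deposited counts on Mp708. Serine proteases made up 7.25% ± 0.112 of the counts on Tx601 and 18.5% ± 1.02 on Mp708 (n = 3 each, exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 libraries allow). Peritrophic membrane and mucin contigs went from 1.55% ± 0.107 to 4.46% ± 0.211, and carbohydrate-digesting contigs from 1.59% ± 0.0445 to 3.58% ± 0.158 (exact p = 0.1 each). In the recount the serine protease share was 13.1% on Tx601 and 16.1% on Mp708 (means of 2 libraries). The peritrophic share was 2.85% and 3.33%, and the carbohydrate share 3.62% and 3.44%. The recounted peritrophic shares overlapped between lines, at 2.448% (Tx601 M) and 3.248% (Tx601 B) against 3.422% (Mp708 E) and 3.244% (Mp708 F). The serine protease and carbohydrate shares did not overlap. Ribosomal proteins went from 4.70% ± 0.491 to 3.09% ± 0.119 in the deposited counts, and from 4.47% to 3.45% in the recount. Lipases and lipid carriers, whose contigs stood higher as a list, had a share of 6.20% ± 0.266 on Tx601 and 5.78% ± 0.00387 on Mp708. In the recount that share lay the other way, 5.40% on Tx601 and 5.87% on Mp708, with no overlap between 2 and 2 libraries. For 19 of the 23 lists the 3 libraries of one line lay on one side of the other line's, where chance gives 10% of lists; shares of one total are not independent of each other.

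**Figure D3:**
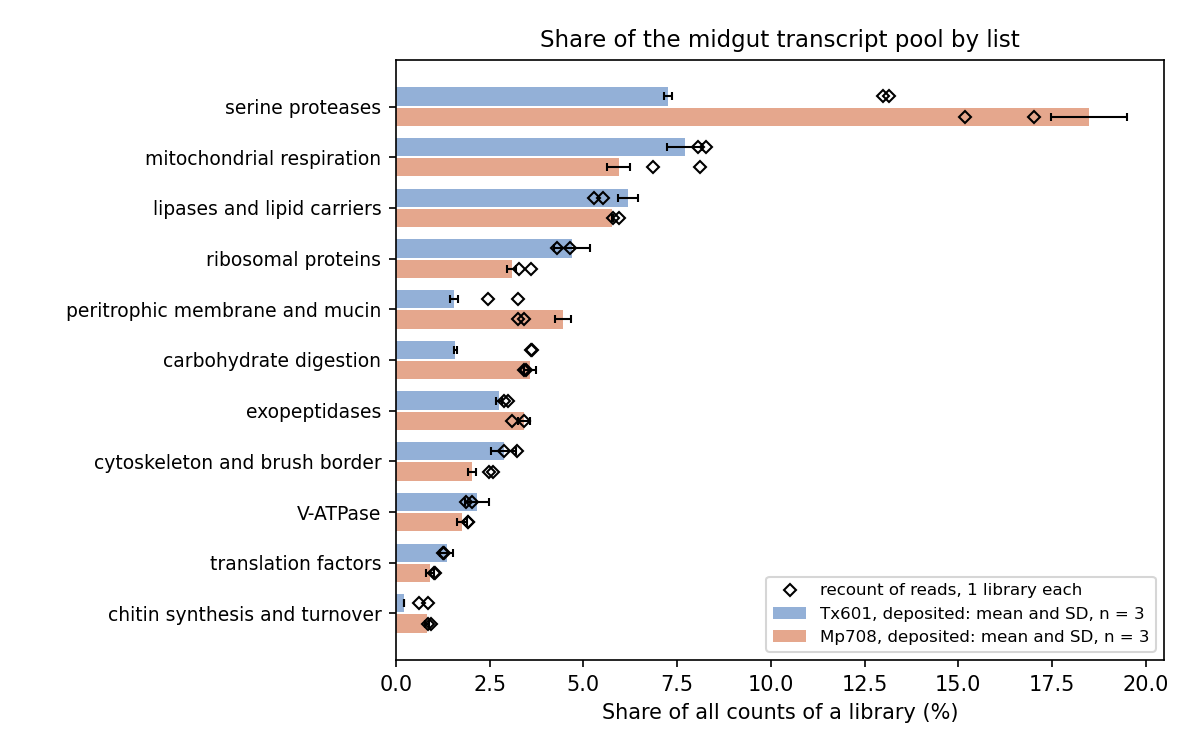
Share of each library's counts that fell in 11 fixed lists. Bars are the mean of 3 deposited columns per line with SD, and open diamonds are single recounted libraries. The serine protease bars stand at 7.25% and 18.5%, and the recounted libraries of both lines lie between them.

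The 5 most abundant contigs had no call. Putative senescence-associated protein (Contig_4444) took 11.03% ± 0.659 of the counts on Tx601 and 7.13% ± 0.754 on Mp708, with a log2 fold of -0.29 (SE 0.11, edgeR adjusted p = 0.545; -0.33 in the recount). The name is that of the deposited table, and the contig was not examined for ribosomal RNA sequence. The others were Contig_788 at 0.18 and Contig_1056 at -0.13, both described as a putative uncharacterized protein, diazepam-binding inhibitor (Contig_308), a carrier of fatty acyl-CoA, at -0.27, and Sui1 (Contig_1809) at 0.28. Their recounted values were 0.13 for Contig_788, -0.04 for Contig_1056, -0.43 for Contig_308 and 0.32 for Contig_1809. Of contigs without a protein name, Contig_5872 and Contig_3379 had the largest rises, 2.57 and 1.85 against -0.55 and -0.08 in the recount, and Contig_2047 and Contig_5459 fell by 0.60 and 0.59, against -1.38 and -0.38.

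On the 500 most variable contigs, the libraries of the 2 lines separated in the deposited counts. The first principal component of the 500 most variable contigs held 45.7% of the variance and placed the Tx601 libraries between -16.9 and -7.15 and the Mp708 libraries between 10.3 and 14.0. Distances between lines were 1.33 times those within lines (exact permutation test over 10 splits, one-sided p = 0.1, the smallest possible). With all tested contigs the ratio was 1.14 (exact p = 0.1), and by rank correlation it was 1.05 (exact p = 0.3). Without the called contigs the ratio was 1.01 (exact p = 0.5). That exclusion takes out contigs picked in these libraries for differing between the lines, so it lowers the ratio by its own rule.

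The called contigs also differed from the rest in how closely libraries of one line matched. Their median coefficient of variation over 3 deposited columns was 2.19% on Tx601 and 1.56% on Mp708, against 13.2% and 12.4% for uncalled contigs of like abundance. Some called contigs with a mean count under 1000 spread less than read sampling gives, at a one-sided p under 0.05. They were 5 of 28 on Tx601 (17.86%) and 2 of 18 on Mp708 (11.11%), against 1.63% and 1.3% of the other contigs. Chance gives 5% for contigs not picked by their spread, but the edgeR test favours a small spread. These counts are also small, so they do not settle whether the spread lies below read sampling. In the recount the 2 libraries of a line differed at the called contigs by a median of 0.20 (Tx601) and 0.28 (Mp708) on the log2 scale, against 0.24 in each line at the uncalled contigs. The deposited columns A and B differed there by 0.04 and E and F by 0.02.

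**Figure D4:**
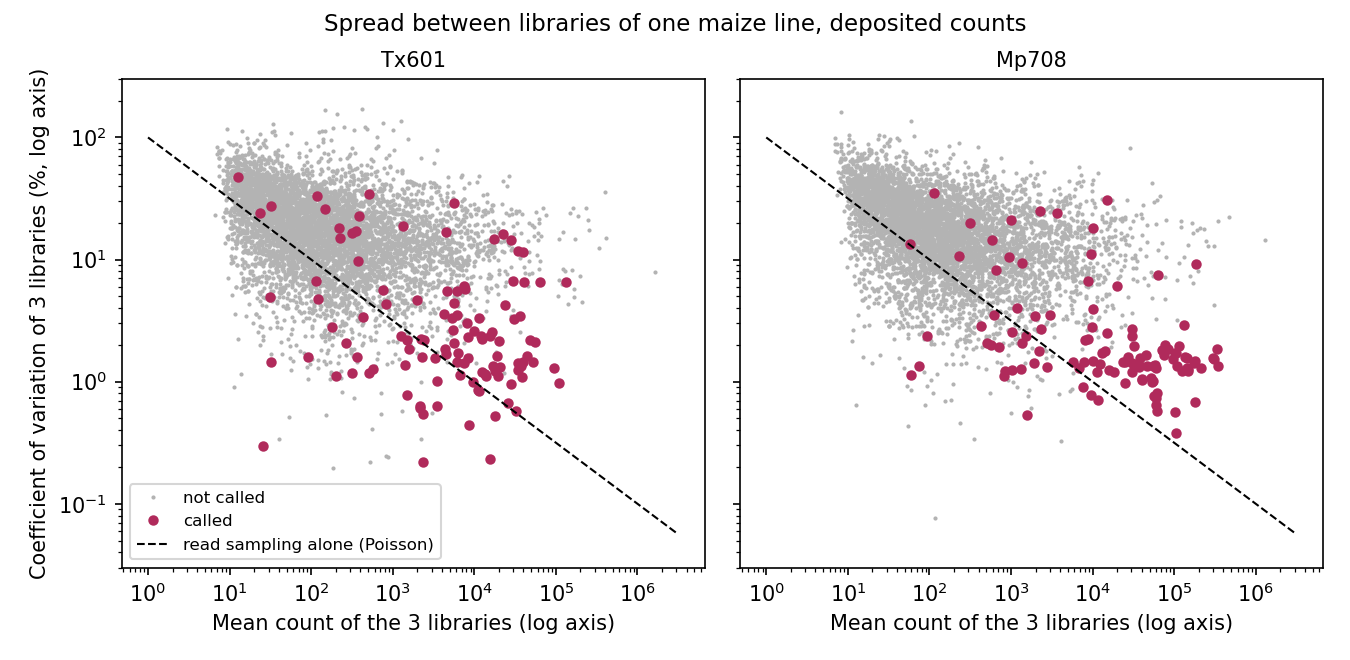
Coefficient of variation of the 3 deposited columns of a maize line (vertical, log axis) against their mean count (horizontal, log axis), 1 point per contig, called contigs coloured. The dashed line is read sampling alone. Most called contigs lie low in the grey cloud or below it, with medians of 2.19% and 1.56%.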

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

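The tests in this part were chosen after the results were seen, except the one on held-out libraries and the other splits of the libraries. No group had 4 or more samples, so single libraries were not screened as outliers.

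The read files, outside the main comparison, gave 27 called contigs, of which 13 were not called over the 6 deposited libraries. In the deposited columns A, B, E and F, however, 23 of the 27 were called, so most of the 13 depend on which libraries enter. A pair of storage protein contigs described as moderately methionine rich shows this: Contig_3092 had a log2 fold of 3.59 in the recount, 3.76 in those columns, -1.46 over 6 libraries and 3.77 without Tx601 C, and Contig_2457 had 4.47, 4.02, -1.22 and 4.73. Antisense reads made up 5.85% (Tx601 M), 6.84% (Tx601 B), 6.18% (Mp708 E) and 6.20% (Mp708 F) of the reads matching a single contig.

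The called contigs differ between deposited counts and deposited reads: the log2 fold gap exceeded 1 for 66 of 113, which include all 11 called peritrophic contigs and 24 of the 35 called serine proteases. Reads shared between similar contigs are argued against as the whole cause, since families of contigs with shared sequence kept a median gap of 1.11 on the log2 scale. Reads missing from the files could raise Mp708 counts (the Mp708 E column exceeds the reads in its file by 996281), but are argued against as the whole cause: for 25% of the rises all 3 Tx601 counts lay below the reads that match that contig alone in both Tx601 files, against 0.28% of other contigs. An effect of the maize line on the transcripts would enter a library's reads and its counts alike, so it cannot make the 2 sources differ. Whether the larvae differ as the deposited counts say stays open. The median log2 fold of the rises, 0.31 in the reads against 2.01, restates the difference and does not tell which source is right. The test on looser matching by the authors did not decide. Of the 42 contigs whose Tx601 counts all lay below the reads matching that contig alone, 33.33% lay below them in Mp708 E and F too. Over the 42, the median log2 of deposited over recounted counts was -1.84 in Tx601 B, 0.09 in Mp708 E and -0.06 in Mp708 F. The 42 contigs were picked for low Tx601 counts, so the low Tx601 B median follows from that choice. The Mp708 medians do not, and they place the shortfall at these contigs mostly in Tx601. They restate the gap there and do not decide on looser matching. Looser matching stays open, since matching at the authors' settings was not run. Any window of 16 colours, stricter than their mapping, gave the rises a median log2 fold of 0.34. Until the cause is known the deposited rises may not describe the larvae.

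Libraries of one maize line also match more closely at the called contigs than elsewhere. A whole library counted more than once is argued against by the lowest mean chi-square per contig within a line, 37.8. That mean runs over all contigs, so it does not tell how the columns relate at the called contigs alone. Contigs called on 4 libraries deviated in the held-out 2 by at most 0.174 of the deviation of other contigs of like abundance. That held over all 9 choices. It argues against selection of contigs whose spread was small by chance in the calling libraries. Contigs with a small spread in every library would give the same result, so selection of such contigs by the test stays open. The close match was strongest where counts and reads differ, with median coefficients of variation of 1.57% (Tx601) and 1.44% (Mp708), against 4.70% and 2.36% for the 47 called contigs with a gap of 1 or less. The cause may be that of the difference between counts and reads, which no test here separates.

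For the count of calls, the real split of the 6 libraries gave 113 and the highest of the other splits 0, so 1 of the 10 splits gave as many. For fixed lists past the camera threshold the real split gave 11 and the highest other 16, and 3 of 10 splits gave as many. The 10 splits are too few for a share under 0.05. The split with 16 lists set Tx601 A and B with Mp708 F.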

How the results depend on the processing

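The recount, the 4-column subset and the exclusion of contigs were chosen after the data were seen. The number of calls, 113, ran from 96 to 123 with a library left out: 96 to 102 of the 113 kept the call, 11 to 17 lost it (3 to 6 of the 38 below) and none changed sign. It ran from 97 to 147 under the other scalings, filters, tests and thresholds, with these exceptions. Total counts alone gave 375 calls, 96 of them higher, against 104 of 113, as the median of all contigs moved by -0.34 on the log2 scale. Summing contigs of one description gave 59, with fewer features tested. The recount gave 27, reads of a single contig 23, any window of 16 colours 37, and the deposited counts without contigs whose counts and reads differ, an exclusion that takes out called contigs by its own rule, 36. The cause of the recount difference is weighed above and was not found.

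Of 11 lists past the camera threshold, 2 held with an estimated correlation, 7 lists passed by fry, which does not compare a list with other contigs, and 6 passed without contigs whose counts and reads differ. With a library left out the number ran from 7 (without Tx601 B) to 16 (without Tx601 C). The 19 lists with separated shares became 19 to 21 with a library left out, 14 in the recount (where chance separates 33.33% of lists, against 10% for 3 against 3), and the distance ratio 1.33 became 1.14 with all contigs and 1.05 by rank correlation; the cause was not tested.

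Of 38 called contigs by the naming rule, 29 lost the call in the recount with the same sign and 7 changed sign there: Contig_5635 to 0.07, Contig_1150 to -0.15, Contig_5872 to -0.55, Contig_3379 to -0.08, Contig_3100 to -0.01, Contig_4248 to -0.15 and Contig_537 to -0.08. The deposited columns A, B, E and F kept the call for 32 of the 38, and the other 6 lost it there and in the recount with these folds: Contig_4735 1.39 and 1.37 (1.30 over 6 libraries), Contig_1544 0.53 and 0.53 (0.66), Contig_3211 -0.83 and -0.81 (-1), Contig_7270 -0.50 and -0.49 (-0.56), Contig_2047 -0.62 and -1.38 (-0.60), Contig_5459 -0.61 and -0.38 (-0.59). A pair of abundant uncalled contigs changed sign with total counts, Contig_788 to -0.17 and Contig_1809 to -0.07. With a library left out, Contig_788 ran from -0.03 to 0.32 and Contig_308 from -0.46 to 0.06. Of the uncalled contigs picked after their values were seen, the storage proteins Contig_3092 and Contig_2457 turned from -1.46 and -1.22 to 3.59 and 4.47 in the recount, 3.76 and 4.02 in columns A, B, E and F and 1.12 and 1.72 by limma-trend. Contig_7751 turned from 0.19 to -0.15 with total counts. With a library left out these 3 ran from -2.05 to 3.77, -1.96 to 4.73 and -0.30 to 2.44, the high values all without Tx601 C, in which the storage proteins had counts of 434 and 1236. Normalized-value pseudocounts and recovered reads did not apply to counts. No paired analysis was possible because the libraries of the 2 lines share no letters.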

Other observations

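The contigs called in the recount, picked after their values were seen, include several of one description; members that were not called were not tallied and no set test was run on these descriptions. The 5 uridine diphosphate glucosyltransferase contigs called there rose, with recounted log2 folds from 2.03 to 2.55, and 3 called contigs of ecdysteroid-regulated protein rose by 2.57 to 2.64, where the deposited counts gave 0.94 to 3.16. A pair of phosphatidylethanolamine-binding protein contigs rose by 1.13 and 1.21, and a pair of juvenile hormone diol kinase contigs fell (Contig_4209 at -1.37 and Contig_3336 at -2.54), the latter not called by the edgeR quasi-likelihood test over 6 deposited libraries (Contig_3336, adjusted p = 0.0546) but called in columns A, B, E and F (0.00715), without Tx601 C (0.0013) and by the edgeR exact test and DESeq2. Contigs of one description may share reads and are not independent. In the recount 14 lists had shares that did not overlap between lines, in 2 against 2 libraries, where chance gives 33.33% of lists. Storage protein contigs, which belong to the fat body list, stood apart in Tx601 C. Contig_3092 had deposited counts of 4, 4 and 434 in Tx601 A, B and C and of 58, 87 and 27 in Mp708 D, E and F, and Contig_2457 had 6, 8 and 1236 and 342, 194 and 48. Without Tx601 C, 16 lists passed the camera threshold against 11 with all 6 libraries.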
